A study of Danio rerio with 12 samples.

How the data were processed

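RNA came from 12 pools of 50 whole zebrafish larvae of the wild-type AB strain, collected at 72 hours after fertilization. The herbicide atrazine was given at 0.3, 3 and 30 ppb, with 0 ppb as control, from about 1 to 72 hours and in 3 pools per dose, per the labels' protocols. Each pool was hybridised to its own single-colour NimbleGen oligonucleotide array after Cy3 labelling. The labels call the pools biological replicates. They do not say whether the pools of 1 dose came from separate clutches, so p-values measure only the spread between these pools.

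The deposited matrix held 385000 features by 12 arrays as linear fluorescence intensities, and the submitters' processing notes name RMA, with the version not given in the sources used here. Several features carried the same target ID, so the deposited intensities had not been summarised to transcripts. Their quantiles were nearly the same on every array, with medians of 529 to 530, a lowest value of 18.0 and a highest of 65226. Background correction, scanner settings, slides and scan dates are not given in the sources used here, so no background call and no slide term could be used. The fixed plan had assumed normalized log2 values. The linear intensities were therefore transformed to log2 first, and the planned tests were kept.

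The platform annotation and RefSeq accessions, with the GRCz12tu gene table used for names only, gave 1 symbol to 30725 features. Several symbols were given to 0 features, and 354275 features had none. Of the named features, 399 from 37 targets were named through their accession only, and updating symbols through the gene ID changed 0 of them. A gene's value was the mean log2 intensity of all features with its symbol, and 13 genes combined 2 targets. A feature with no symbol was averaged under its target ID. This gave 37144 units, of which 2650 were genes with a symbol and 34494 were targets unnamed here. The median number of features per unit was 12, with a range of 1 to 24. All units were tested, with no filter on dim values.

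Group means were fitted over all 12 arrays with limma 3.58.1 (lmFit, contrasts.fit and eBayes with default settings) in R 4.3.3, with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 for reading and naming. Benjamini-Hochberg adjustment ran over all 37144 units, with a threshold of 0.05. Each dose was compared with 0 ppb, the mean of the 3 doses with 0 ppb, and the doses with each other. A trend was fitted as a slope over the rank of the dose. The tests, the named-gene rule, 36 gene lists and the alternatives were fixed before the data were examined.

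The lists held 636 different genes, of which 75 (11.8%) were measured under a symbol. limma's camera, with a preset inter-gene correlation of 0.01, compared each list with the other named genes, adjusted over the lists tested. It was run on the 11 lists with at least 3 measured members. That minimum was set once the coverage was known and before any list was tested. A further 21 lists were written after the gene names on the array, and 8 of the named genes near the top of a comparison of doses, had been seen.

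The genes named are, for each dose and for the mean of the doses, the 10 largest rises and falls past the threshold with no overlap between treated and control pools. Where fewer passed, up to 5 per direction were taken by size of change from genes with an unadjusted p under 0.01 and no overlap, and these are reported as not past the threshold. Up to 4 members of each list past its test were added. So were up to 3 members of the lists on hormones, steroidogenesis, aryl hydrocarbon receptor genes, mitosis and DNA replication, whatever they showed. For the trend and the comparisons between doses, the 5 largest changes past the threshold in each direction were taken. Symbols that only repeat a clone ID were counted and not named.

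The fits were tested on simulated data with the real means and spreads. Among 37144 units, a change at 30 ppb was recovered for 7.8% of units at 1.5-fold, 69.0% at 2-fold and 98.2% at 4-fold. A trend was recovered for 15.5%, 77.0% and 99.4% of units at the same folds between the lowest and highest dose. Camera found a shift of 0.5 on the log2 scale at 30 ppb in 100 of 100 simulated lists of 6 genes, and called 2 of 100 unshifted lists. The genes were simulated as independent of each other, so neither count shows how camera performs on lists of correlated genes. The number of arrays limits the precision.

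The alternatives tried were another summary of features, other normalizations, a filter on dim units, array quality weights, looser thresholds, a replicate block and leaving out each pool in turn. After the data had been seen, each array's probe-position gradient was added as a covariate. The gradient is the slope of intensity, relative to the mean of the arrays, along the number at the end of each feature's ID. That number was read as the position of the feature within its target, which no table used here states, so every result on the gradient rests on this reading. It was computed over 260732 features of 24155 targets with at least 6 features spanning at least 500 positions.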

Results

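Gene expression was measured in whole zebrafish larvae after exposure to atrazine during embryonic development, to learn which transcripts the herbicide altered and whether genes of neuroendocrine, reproductive, cell cycle and cancer-related function were among them. The 12 arrays comprised 3 pools of 50 larvae at each of 0, 0.3, 3 and 30 ppb. Median intensities lay between 529 and 530 on all arrays. Values below are log2 intensities as mean ± SD over 3 pools, and changes are fitted log2 differences from 0 ppb with their standard error (SE).

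At 0.3 ppb no gene passed the threshold. With no overlap between the groups and an unadjusted p under 0.01, 1 gene with a symbol was lower and 1 higher. The lower was mybpc1, which encodes a myosin-binding protein of skeletal muscle. Its level was 9.94 ± 0.18 against 10.42 ± 0.03 at 0 ppb, a change of -0.48 (SE 0.14, adjusted p = 1), and all 9 of its features were lower. The higher was or91a3, an odorant receptor gene, with a change of 0.37 (SE 0.12, adjusted p = 1). Neither was past the threshold. Larger changes of other genes, such as -0.80 for prss59.1 (SE 0.51) and 0.60 for hbbe3 (SE 0.32), did not meet this rule (unadjusted p of 0.144 and 0.0897). The luteinizing hormone beta subunit gene lhb differed by 0.33 (SE 0.26), the vasopressin gene avp by 0.17 (SE 0.16) and the hypocretin gene hcrt by 0.13 (SE 0.22), each with an adjusted p of 1. limma called 0 of 37144 units, and 551 units had an unadjusted p under 0.05, where 1857 would be expected by chance. Units vary together across arrays, so such a count can lie far from 1857 by chance alone. The largest axis of variation between the arrays held 41.4% of the variance. Dose groups explained 4.4% of it, so most of it stayed in the error term of these fits. At no dose does a count below 1857 therefore show that no unit changed.

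At 3 ppb the hypothalamic and pituitary hormone list shifted upward. The median change of its 6 measured members was 0.42 (camera adjusted p = 4.15e-09, and adjusted p = 0.0143 with an estimated correlation). The largest change was in lhb, which encodes the beta subunit of the pituitary hormone that acts on the gonads, at 7.39 ± 0.69 against 5.94 ± 0.05, or 2.72-fold (log2 change 1.44, SE 0.26, adjusted p = 0.244). The vasopressin gene avp, expressed in the hypothalamus, was at 9.37 ± 0.19 against 8.74 ± 0.19 (change 0.63, SE 0.16, adjusted p = 0.747). The somatolactin genes smtla and smtlb, which encode pituitary hormones of fish related to growth hormone and prolactin, differed by 0.51 (SE 0.15, adjusted p = 1) and 0.33 (SE 0.19, adjusted p = 1). The other 2 members moved little, with 0.22 for hcrt (SE 0.22), whose pools overlapped those at 0 ppb, and 0.00 for the thyrotropin-releasing hormone gene trh (SE 0.27), so the shift was not shared by the whole list. Adjusted over the list alone, 3 of the 6 genes passed, but the list was picked out by its shift in these same values. Over the 75 measured genes of all fixed lists only lhb passed, and over all units 0 did.

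With no overlap between the groups and an unadjusted p under 0.01, 8 genes with a usable symbol were higher at 3 ppb and 0 were lower. Chance alone keeps 3 pools apart from 3 others in 10% of genes. That share counts both directions and asks for no p, so it is not the baseline for the 8. They came from 2650 genes with a symbol, less 192 whose symbol is a clone or locus ID. After lhb, the 4 largest changes were in npffl, a neuropeptide FF-like gene (change 0.79, SE 0.16), the globin gene ba1l (0.69, SE 0.17), the interleukin 12 subunit gene il12a (0.69, SE 0.20) and tmigd1 (0.64, SE 0.16). Their adjusted p lay at 0.372, 0.732, 1 and 0.732, so none passed. All 12 features of npffl were higher, against 5 of 9 for tmigd1. limma called 0 units at 3 ppb, and 1123 had an unadjusted p under 0.05, of which 71.2% were higher. By chance 1857 would be expected. With array quality weights 1193 units were called, 605 higher and 588 lower, in a fit whose weights raised a convergence warning. Taking the median of a gene's features gave 3 calls, and testing every feature on its own gave 1.

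At 30 ppb the hormone list was again shifted upward, with 5 of 6 members higher and a median change of 0.32 (camera adjusted p = 1.84e-08, and adjusted p = 0.0181 with an estimated correlation). The level of lhb was 7.36 ± 0.25 against 5.94 ± 0.05, or 2.67-fold (change 1.42, SE 0.26, adjusted p = 0.179). That of smtla was 7.18 ± 0.18 against 6.54 ± 0.04 (change 0.64, SE 0.15, adjusted p = 0.542). The changes of avp and smtlb were 0.49 (SE 0.16, adjusted p = 1) and 0.16 (SE 0.19, adjusted p = 1), and those of hcrt and trh 0.10 (SE 0.22) and -0.11 (SE 0.27). Adjusted over the list alone, 3 of the 6 genes passed, and over the 75 measured genes of all fixed lists lhb and smtla did. limma's fry, which asks whether the genes of a list move on balance in 1 direction, gave an adjusted p of 0.0753 for the list at 30 ppb and 0.0326 at 3 ppb. Of the 6 genes, 5 lay below the median level of all units, with lhb brighter than 19.6% of units, and avp was brighter than 51.1%.

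**Figure D1:**
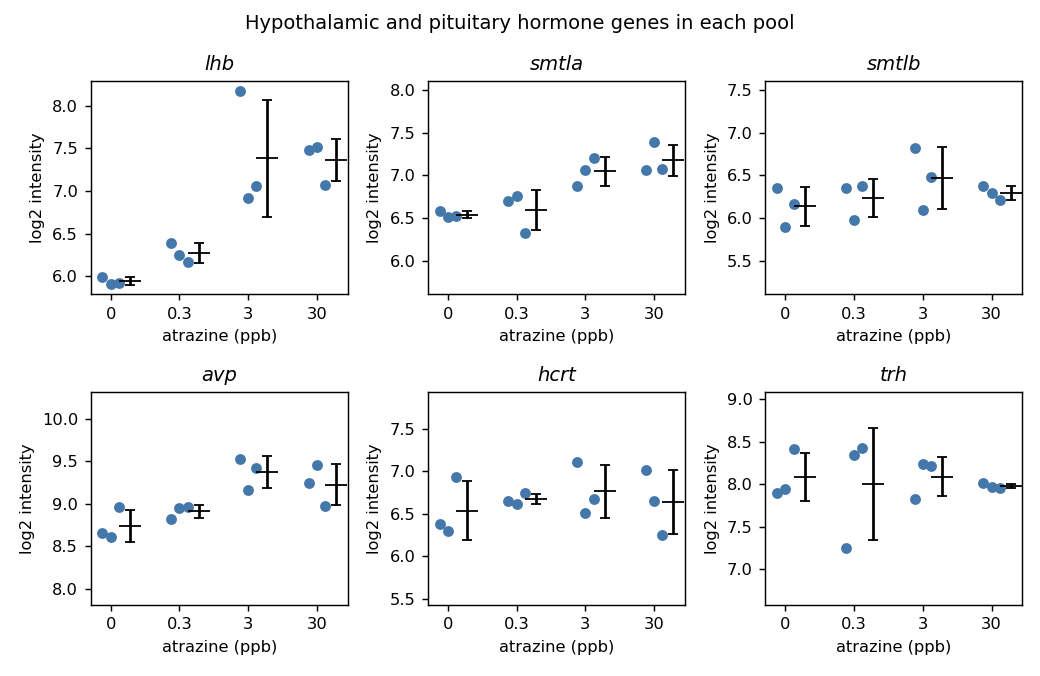
Log2 intensity (vertical axis) of the 6 measured hypothalamic and pituitary hormone genes in each pool, by atrazine dose in ppb (horizontal axis). Points are pools, bars are mean ± SD (n = 3), and all panels span the same range of log2 units; for lhb all 3 pools at 3 ppb and at 30 ppb lie above all pools at 0 and 0.3 ppb.

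Among other named genes at 30 ppb, npffl (change 0.72, SE 0.16, adjusted p = 0.41), tmigd1 (0.69, SE 0.16, adjusted p = 0.511) and the odorant receptor gene or41a2 (0.66, SE 0.20, adjusted p = 1) were highest after lhb among those with no overlap and an unadjusted p under 0.01. They were not past the threshold. In the other direction stood vgll2a, a transcription cofactor gene of developing muscle (change -0.47, SE 0.15), and abhd13 (-0.41, SE 0.13), each with an adjusted p of 1. All 11 features of vgll2a and 11 of 12 features of abhd13 were lower. limma called 0 units, with 928 at an unadjusted p under 0.05, where 1857 would be expected by chance. Of the 928, 81.4% were higher. Array quality weights gave 354 calls with a convergence warning, the probe-position gradient as a covariate gave 20, the median of features 2 and the replicate block 1.

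Genes of steroid synthesis, the aryl hydrocarbon receptor, mitosis and DNA replication showed no change past the threshold at any dose, with 1 gene measured for each list. The estrogen-forming hydroxysteroid dehydrogenase gene hsd17b1 differed by 0.17 (SE 0.25) at 0.3 ppb, -0.14 (SE 0.25) at 3 ppb and 0.11 (SE 0.25) at 30 ppb. The changes of cyp1b1, a target of the aryl hydrocarbon receptor, were 0.22, 0.10 and 0.14 (SE 0.14 for each). The cyclin A2 gene ccna2 differed by 0.01, 0.01 and -0.13 (SE 0.17 for each), and the replication helicase gene mcm5 by -0.04, -0.02 and -0.12 (SE 0.16 for each). All 12 adjusted p-values were 1. In the simulations with 3 pools per dose, a 1.5-fold change at 30 ppb mostly failed to pass over all units. The lack of a call therefore does not exclude small changes. The precision for each of these genes is given by its own SE.

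The other 10 lists tested did not pass at any dose. For the lens, with 8 genes, 7 were lower at 0.3 ppb, while 6 were higher at 3 ppb and 5 at 30 ppb. Medians were -0.06, 0.05 and 0.02, with adjusted p of 0.795, 0.513 and 0.871. For cholesterol synthesis, with 7 genes, medians were -0.04, 0.07 and 0.00 (adjusted p 0.992, 0.695 and 0.871). The 4 genes of innate immune cells and inflammation were all lower at 3 ppb (median -0.13, adjusted p = 0.41), as were the 4 pigment cell genes (median -0.19, adjusted p = 0.513). The 3 genes of dopamine and serotonin signalling (drd2a, drd3 and fev) were all lower at 0.3 ppb, with a median of -0.19 (adjusted p = 0.158). The lists on cancer-associated genes, heart, intestine, cartilage and bone, and heat shock and unfolded protein response, with 3 genes each, had adjusted p of at least 0.513 at every dose. A list's median, mean and test differed in sign in 11 of the 33 combinations of list and dose, none of them past the threshold.

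**Figure D2:**
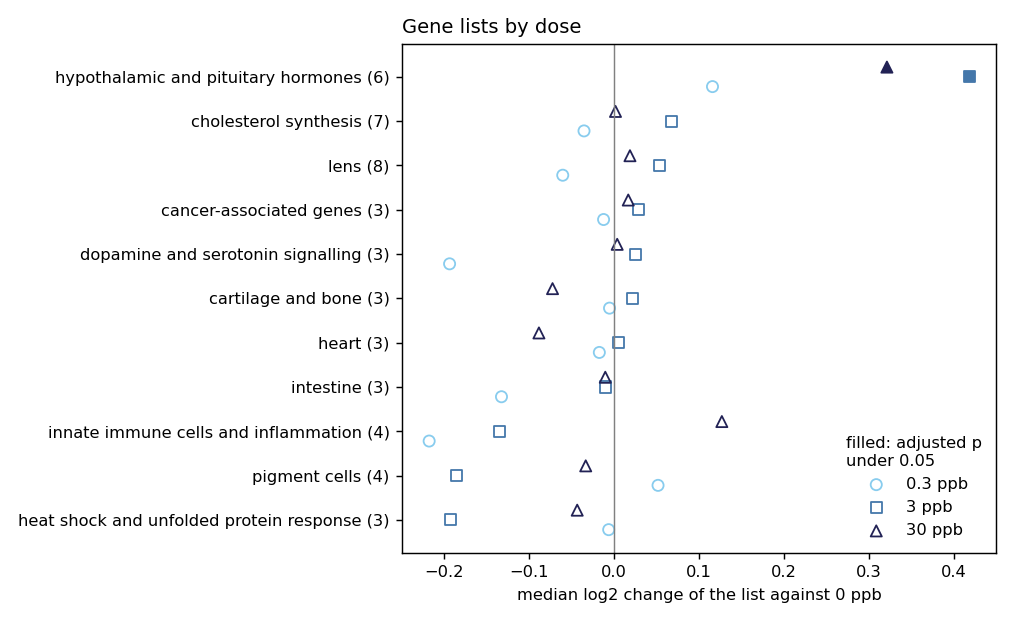
Median log2 change against 0 ppb (horizontal axis) of each of the 11 gene lists tested (vertical axis, number of measured genes in brackets) at 0.3, 3 and 30 ppb. Filled symbols mark lists with a camera adjusted p under 0.05, which are the hormone list at 3 ppb (median 0.42) and at 30 ppb (median 0.32).

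A further 19 lists had 1 or 2 measured genes and were not tested as lists. Besides the lists on steroid synthesis, the aryl hydrocarbon receptor, mitosis and replication, these covered germ cells, estrogen-responsive, glucocorticoid-responsive, xenobiotic and oxidative stress genes. They also covered p53 targets, neurons, glia, photoreceptors, fast muscle, exocrine pancreas, red blood cells, the circadian clock, oxidative phosphorylation and ribosomal proteins. Over their 28 genes and all 3 doses the smallest unadjusted p was 0.0897. No gene was measured under a symbol for 6 lists (thyroid axis, liver, hatching gland, epidermis, fatty acid metabolism, and glycolysis), which are not analysed here.

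In the mean of the 3 doses the hormone list was higher than at 0 ppb, with 5 of 6 genes higher and a median change of 0.30 (camera adjusted p = 1.46e-08, and adjusted p = 0.0174 with an estimated correlation). With fry the list did not pass (adjusted p = 0.0821). Of the 4 named genes with no overlap and an unadjusted p under 0.01, lhb changed most, by 1.06 (SE 0.21, adjusted p = 0.606). It was followed by ba1l (0.52, SE 0.14), or41a2 (0.51, SE 0.16) and the muscarinic acetylcholine receptor gene chrm5a (0.45, SE 0.12), each with an adjusted p of 1. For avp, smtla and smtlb the changes were 0.43 (SE 0.13), 0.40 (SE 0.12) and 0.20 (SE 0.16), also with an adjusted p of 1. The 4 genes named for the other lists differed by 0.05 for hsd17b1 (SE 0.20), 0.15 for cyp1b1 (SE 0.12), -0.04 for ccna2 (SE 0.14) and -0.06 for mcm5 (SE 0.13). limma called 0 units, with 801 at an unadjusted p under 0.05, and 24 with array quality weights.

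Over the ordered doses, 36 units rose and 0 fell (limma, adjusted p under 0.05). The only one with a symbol was lhb, which rose by 0.54 per dose step (SE 0.09, adjusted p = 0.0487), from 5.94 at 0 ppb to 6.27, 7.39 and 7.36. The other 35 were targets unnamed here. The units were selected for this rise, so the values that follow only describe them. The median unit was 1.18-fold higher than control at 0.3 ppb, 1.97-fold at 3 ppb and 2.19-fold at 30 ppb. In 31 of the 36 units all pools at 3 and 30 ppb lay above all pools at 0 and 0.3 ppb. They were dim, at a median log2 intensity of 7.05, above 23.4% of all units.

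The trend depended on single pools. The count was 0 without replicate 2 of the 0.3, 3 or 30 ppb group or without replicate 3 of the 0 or 3 ppb group. It was 1 without 0 ppb replicate 2, 5 without 30 ppb replicate 3, 23 without 0.3 ppb replicate 3 and 58 without 3 ppb replicate 1. The call of lhb was lost in 11 of the 12 fits that left out a pool, with adjusted p of 0.0605 to 0.244. In these 11 fits its slope stayed between 0.53 and 0.60. The remaining fit kept the call, with a limma adjusted p of 0.00149. With dose in ppb as a number, 0 units were called. With the median of features 14 were called, of which 9 were among the 36, and with cyclic loess 36, of which 27 were.

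**Figure D3:**
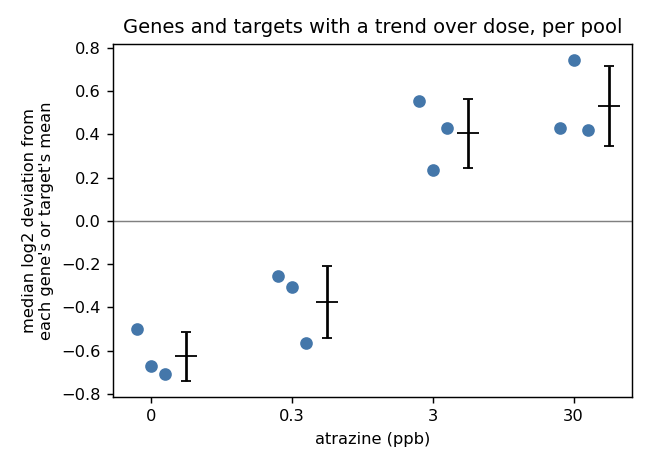
Median deviation, over the 36 units with a trend, of the log2 intensity from each unit's mean over the 12 arrays (vertical axis), by atrazine dose in ppb (horizontal axis). Points are pools and bars are mean ± SD (n = 3); the pools at 0 and 0.3 ppb lie between -0.71 and -0.26 and those at 3 and 30 ppb between 0.24 and 0.74.

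Between doses, the hormone list was higher at 3 than at 0.3 ppb in all 6 genes, by a median of 0.34 (camera adjusted p = 3.16e-05, and adjusted p = 0.0761 with an estimated correlation). It was higher at 30 than at 0.3 ppb in 4 of 6 genes, by a median of 0.19 (adjusted p = 0.000498, and adjusted p = 0.151 with an estimated correlation). None of the 11 lists fixed in advance differed between 30 and 3 ppb, where the smallest adjusted p was 0.0665, for the innate immune list. Single units gave 0 calls by limma between 3 and 0.3 ppb, between 30 and 0.3 ppb, and between 30 and 3 ppb, with 1544, 1514 and 283 at an unadjusted p under 0.05. Array quality weights gave 17, 61 and 2212 calls. Between 30 and 0.3 ppb, the replicate block gave 3 calls, and the median of features and the gradient covariate gave 1 each.

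The log2 changes at 3 and 30 ppb correlated across all units with r = 0.68 and had the same sign in 69.6% of units. Between 0.3 and 3 ppb r was 0.36 (61.9% of the same sign) and between 0.3 and 30 ppb it was 0.24 (56.6%). These values were not stable. With dim units left out they were 0.499, 0.231 and 0.045 in this order, and with a control pool left out they reached 0.766, 0.594 and 0.49. Units are not independent replicates, and the comparisons share the 3 control pools. In 100 simulations of unchanged groups with shared controls, the median r was 0.53 for 3 and 30 ppb, 0.48 for 0.3 and 3 ppb, and 0.52 for 0.3 and 30 ppb. The simulated 95% range for 3 and 30 ppb, -0.22 to 0.91, contained the observed value. The covariance was 0.0238 for 3 and 30 ppb against a simulated median of 0.0205, 0.0117 against 0.0212 for 0.3 and 3 ppb, and 0.0074 against 0.0205 for 0.3 and 30 ppb. The 3 controls were too few to split, so part of any excess may come from the shared controls.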

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

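Several tests below were chosen after the result was seen. These were those on the main axis of variation, the gradient test of the trend and the hormone list without lhb. So were the regroupings for the trend and for 3 and 30 ppb together. The gradient covariate and the grouping of doses used for the hormone list also came after the data had been seen. The gradient rests on reading the number at the end of a feature's ID as its position. Groups of 3 pools were too small for a search for outlying samples. A test of the difference between doses set apart 3 results. The hormone list differed between 3 and 0.3 ppb by a median of 0.343 and between 30 and 0.3 ppb by a median of 0.186, but neither difference passed with an estimated correlation (adjusted p = 0.0761 and 0.151) or with fry (0.142 and 0.296). The list on dopamine and serotonin signalling was higher at 3 than at 0.3 ppb in 3 of 3 genes, by a median of 0.207 (camera adjusted p = 0.0246, and adjusted p = 0.233 with an estimated correlation).

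Of the 6 hormone genes, 5 were higher at 3 and 30 ppb combined than at 0 and 0.3 ppb combined, and the median difference of the list was 0.333, a grouping noticed in the data. The median exceeded that of all 10000 random lists of named genes matched on mean intensity (percentile 100, highest random median 0.286). With each array's probe-position gradient as a covariate 112.9% of this median remained. The gradient overlapped widely between these groups of doses, so the covariate could remove little of any difference between them. The 31 synaptic and neurotransmission genes had a median of -0.009 (95% bootstrap interval -0.071 to 0.021). This was short of the 0.166 set as the mark of a larger share of neural tissue. Synaptic genes do not track pituitary cells, so for lhb, smtla and smtlb the share of such cells was not tested. With the preset correlation, the list without lhb still passed at 3 ppb (camera adjusted p = 2.3e-05) and 30 ppb (0.000158). At least as many lists were called in 6 of 10 regroupings of the pools at 3 ppb and 8 of 10 at 30 ppb, the real one included. A response of pituitary and hypothalamic genes to atrazine may underlie the shift, as a hypothesis found and tested on the same data. Chance was not excluded, and differences in developmental timing, cell shares or slides between pools stay open as untested.

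The main axis of variation between the 12 arrays held 41.4% of the variance. It followed the probe-position gradient of the arrays, with Pearson r = 0.879 (permutation p = 0.00024) and Spearman rho = 0.909 (permutation p = 0.00011) over 12 arrays. Without the 2 arrays farthest from the median gradient, r was 0.854. Dose groups explained 4.4% of the axis, below the median of 23.9% for random groups of the same sizes, which argues against dose as its source. Replicate numbers explained 50.0%, above 95.3% of random groupings, so RNA quality, labelling or a shared handling of pools are candidate sources, and the gradient alone cannot separate them.

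The units that rose over dose kept 99.5% of their median slope with the gradient as a covariate. The gradient itself did not follow the order of doses. It ranged from -0.1028 to 0.0728 at 0 ppb, -0.1249 to 0.0573 at 0.3 ppb, -0.1446 to 0.1008 at 3 ppb and 0.0109 to 0.0671 at 30 ppb. The covariate could therefore remove little of any slope over dose. It is this lack of order, not the 99.5%, that argues against the gradient as the cause. In 25 of the 36 units at least 80% of the features rose. The units were selected for a rise in the mean of these same features, so a high share is partly built in. It therefore does not decide whether the signal came from a single part of the sequence. With the median of features, 9 of the 36 were called. Chance was not excluded: 6 of 100 regroupings of the 12 arrays, the real one included, gave at least 36 calls, and the highest of the others gave 9179. The 5 that exceeded the real count correlated with the main axis of variation at 0.688 to 0.895 in absolute value, which points to a structure of the samples, although 2 others with -0.712 and 0.695 gave 0 calls and 1 with 0.46 gave 33; the real dose order stood at 0.052.

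For the comparisons of 3 pools with 3, only 10 regroupings exist, too few for a share under 0.05. The counts of units were 0 at 0.3, 3 and 30 ppb, between 30 and 0.3 ppb and between 30 and 3 ppb, with 0 as the highest of the other regroupings in each, so all 10 were as large. Between 3 and 0.3 ppb the real count was 0 and the highest other 1610, which also points to a structure of the samples. For the mean of the doses the real count was 0, so all 100 regroupings drawn were as large, with 2745 as the highest other. For the lists, the real counts were 0, 1 and 1 at 0.3, 3 and 30 ppb, the highest others 1, 3 and 3, and 10, 6 and 8 of the 10 regroupings were as large.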

How the results depend on the processing

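The gradient covariate and the hormone list without lhb were chosen after seeing the data. At 0.3 ppb the count of units stayed at 0 under every alternative except the unadjusted threshold with 1.5-fold, and leaving out single pools kept it at 0 in every comparison against 0 ppb and between doses. Unadjusted p under 0.05 with at least 1.5-fold gave 99, 364 and 297 units at 0.3, 3 and 30 ppb, 134 in the mean of the doses, 12 for the trend, and 417, 398 and 31 for 3 against 0.3, 30 against 0.3 and 30 against 3 ppb. Array quality weights gave 1193 and 354 at 3 and 30 ppb, 24 in the mean, 190 for the trend, and 17, 61 and 2212 between doses, with a convergence warning in each fit except the trend. The median of features gave 3, 2, 14 and 1 at 3 ppb, at 30 ppb, for the trend (9 of them among the 36) and for 30 against 0.3 ppb. Every feature on its own gave 1 at 3 ppb and 100 for the trend. The gradient covariate gave 20 at 30 ppb, 85 for the trend and 1 for 30 against 0.3 ppb, and an adjusted p under 0.1 gave 10 at 30 ppb and 60 for the trend. The trend count was 0 with units below the median level left out, 0 for genes with a symbol only and 0 with dose in ppb as a number, and ranged from 0 to 58 over pools left out. The 36 units had a median level above only 23.4% of all units, and only lhb had a symbol. Leaving out dim units or unnamed targets therefore took most of the 36 out of the test. Apart from this and from fewer pools tested, the cause of the moved counts was not tested.

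The replicate numbers did not meet the rule for pairing, under which every same-numbered pair correlates above 0.1: 9 of 18 pairs did (-0.371 to 0.679), and 6 of 12 arrays matched their own number best. Some same-numbered pools did deviate together, with 0.431 to 0.524 among the 3 treated pools of replicate 1 and 0.639 to 0.679 among replicate 2 at 0, 0.3 and 3 ppb, so a handling shared by part of the pools stays open. With the replicate block the counts were 1 at 30 ppb, 3 for 30 against 0.3 ppb and 45 for the trend, and it was 150 for 3 and 30 ppb together against 0 and 0.3 ppb together (100 of the 103 called without the block among them). The other counts of units and lists that were refitted with the block stayed as they were.

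With camera's preset correlation, the hormone list passed with any single pool left out. The camera adjusted p was 1.71e-09 to 2.03e-06 at 3 ppb and 3.36e-10 to 6.34e-05 at 30 ppb. With no pool left out, the adjusted p with an estimated correlation was 0.0143 at 3 ppb and 0.0181 at 30 ppb. With fry it was 0.0326 and 0.0753. How far the results with an estimated correlation or fry depend on single pools was not tested. The count of lists became 0 at 3 and at 30 ppb with units below the median level left out, since fewer than 3 hormone genes remained to be tested. It became 0 at 30 ppb with fry, 2 at 3 ppb with the median of features (dopamine and serotonin added) and 1 at 0.3 ppb with the gradient covariate (the same list). Over pools left out it ranged from 1 to 2 at 3 ppb (lens added without 3 ppb replicate 1 or 0 ppb replicate 2) and at 30 ppb (innate immune genes added without 30 ppb replicate 2). The correlations between doses were 0.231 (0.3 and 3 ppb), 0.045 (0.3 and 30 ppb) and 0.499 (3 and 30 ppb) with dim units left out, and 0.398 to 0.594, 0.385 to 0.49 and 0.733 to 0.766 over control pools left out.

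Of 929 alternative values of single named genes, 855 kept direction and side of the threshold, 20 newly passed, 25 no longer passed and 29 changed sign, all of these of genes not past the threshold. Array quality weights turned ccna2 to -0.086 at 0.3 ppb, 0.029 at 30 ppb and 0.032 in the mean, and hsd17b1 to -0.037 at 30 ppb. The median of features turned hsd17b1 to -0.03 at 30 ppb and -0.102 in the mean, cyclic loess turned it to -0.028 in the mean, and the gradient covariate turned mcm5 to 0.005 at 0.3 ppb. Over pools left out, hsd17b1 ranged from -0.096 to 0.311 at 0.3 ppb, -0.136 to 0.247 at 30 ppb and -0.075 to 0.172 in the mean, and cyp1b1 from -0.058 to 0.202 at 3 ppb. ccna2 ranged from -0.067 to 0.119 at 0.3 ppb, -0.103 to 0.097 at 3 ppb and -0.087 to 0.047 in the mean, and mcm5 from -0.139 to 0.162, -0.061 to 0.019 and -0.092 to 0.008 in these comparisons. No background measure was used here, so how far dim units such as lhb stand above background is unknown.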

Other observations

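The comparison of 3 and 30 ppb with 0 and 0.3 ppb, and the lists below, were chosen after the data or the gene names had been seen. For single units, this comparison was fitted with a single mean for each pair of doses, not with a mean per dose. Differences between the doses of a pair thus counted as spread between pools. At 3 and 30 ppb together, 103 units were higher and 0 lower than at 0 and 0.3 ppb together (limma, adjusted p under 0.05), 5 of them with a symbol. These were lhb (change 1.27, SE 0.18, adjusted p = 0.00663), npffl (0.69, SE 0.11, adjusted p = 0.0131), tmigd1 (0.65, SE 0.10, adjusted p = 0.014), smtla (0.55, SE 0.10, adjusted p = 0.0359) and 1 gene known by a clone ID. For avp the change was 0.47 (SE 0.11, adjusted p = 0.134). Of the 36 units with a trend, 33 were among the 103. The count was 54 with the median of features, of which 39 were among the 103, and 4 with units below the median level left out. It was 50 to 109 over pools left out, 140 with cyclic loess, 150 with the replicate block, 182 with array quality weights (6 of them lower) and 254 with the gradient covariate (2 of them lower). In 1 of 100 regroupings of the arrays into 6 and 6, the real one, the count was as large (real 103, highest other 0). The grouping was picked because these pools were seen to separate, so the regroupings do not decide whether chance made it.

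Among the further lists, all 22 odorant and taste receptor genes were higher at 3 ppb (median 0.22, camera adjusted p = 1.04e-09, and adjusted p = 0.703 with an estimated correlation). At 30 ppb all 22 were higher too (median 0.12, adjusted p = 2.76e-07, and 0.926 with an estimated correlation), and at 0.3 ppb 18 were (median 0.09, adjusted p = 0.0105, and 0.823 with an estimated correlation). They were dim, at a median log2 intensity of 5.79, and their median stood at percentile 99.71, 91.35 and 11.96 of random lists matched on intensity at 3, 30 and 0.3 ppb. The 29 cytokine and innate immunity genes were higher in 24 at 30 ppb (median 0.15, adjusted p = 1.1e-06, and 0.926 with an estimated correlation; percentile 99.8). They were higher in 19 at 3 ppb (median 0.10, adjusted p = 0.00366, and 0.724 with an estimated correlation) and in 19 at 0.3 ppb (median 0.06, adjusted p = 0.0402, and 0.823 with an estimated correlation), at percentile 79.06 and 33.03 only. Of 33 striated muscle genes, 28 were lower at 0.3 ppb (median -0.12, adjusted p = 8.87e-05, and 0.663 with an estimated correlation), below all matched random lists. At 3 and 30 ppb 24 and 25 of them were lower, and the list did not pass (camera adjusted p = 0.462 and 0.212). Of 28 clustered protocadherin genes, which encode neuronal adhesion proteins, 24 were lower at 3 ppb (median -0.15, adjusted p = 0.00138, and 0.724 with an estimated correlation), below all matched random lists. At 0.3 ppb 21 of them were higher (median 0.07, adjusted p = 0.222), and they were lower at 3 than at 0.3 ppb (median -0.27, adjusted p = 2.55e-05, and 0.961 with an estimated correlation) and higher at 30 than at 3 ppb (median 0.10, adjusted p = 0.0025, and 0.966 with an estimated correlation). A list of 16 peptide hormone genes outside the first hormone list, written when its member npffl had been seen to separate the doses, was higher in 11 genes at 3 ppb (median 0.10, adjusted p = 0.0122, and 0.724 with an estimated correlation; percentile 90.71 of matched lists) and in 11 at 30 ppb (median 0.06, adjusted p = 0.0262, and 0.926 with an estimated correlation; percentile 84.5). Of 24 lens genes in a wider list, 20 were higher at 3 ppb (median 0.08, adjusted p = 0.0217, and 0.724 with an estimated correlation). At 0.3 and 30 ppb 13 and 17 of them were higher, and this list did not pass (camera adjusted p = 0.731 and 0.119). None of these calls held with an estimated correlation.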
